A study of Homo sapiens with 4 samples.

How the data were processed

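Gene expression was measured by RNA sequencing in 4 libraries of the uveal melanoma line OMM2.3, grown with 10% fetal bovine serum, 1 each for control, CCCP, DHA and both compounds. Per the labels' protocols, libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. The authors deposited FPKM (fragments per kilobase of exon, scaled to library size) for 58735 genes per library, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here. All gene identifiers, and 58708 of the names, matched GENCODE 29 (Ensembl 94, GRCh38), from which gene types and coordinates were taken.

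From the values, FPKM multiplied by the summed exon length of each gene in GENCODE 29 was a whole multiple of 1 step per library for 100% of genes above 0, within a tolerance of 0.01 reads, which gave back whole reads. The library sizes implied by these steps matched median-of-ratios size factors, with a largest difference of 7.58e-09 percent, and differed from the summed reads by at most 2.78%. The deposited values thus already carried a scaling between libraries, and they were used as deposited. Recovered reads served for depth, counting intervals and 2 of the alternatives. Genes with few reads are given with their reads or their wide intervals.

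Ratios were taken on log2(FPKM + 0.5) over 13678 genes with at least 1 FPKM in at least 1 library. The 5 comparisons between 2 libraries had no test, and a gene was counted as higher or lower at a ratio of at least 2-fold. Fold differences given with an interval are ratios of FPKM without the pseudocount, with exact 95% Clopper-Pearson intervals of the conditional binomial. The number of 2-fold genes expected from counting noise alone came from 20 simulated draws of unchanged libraries. The 2 factors were tested with limma-trend on log2(FPKM + 0.5) in an additive model with 1 residual degree of freedom, with Benjamini-Hochberg adjustment at 0.05, and the fit was tested on simulated data with 200 genes changed per factor. Shares of variation came from the 3 orthogonal contrasts of the 4 libraries.

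The 38 gene lists were fixed, with the comparisons, tests, rule for named genes and the first set of alternative settings, before the data were examined. They covered the integrated stress response, endoplasmic reticulum chaperones, mitochondrial chaperones, mitophagy, autophagy, lysosome, oxidative phosphorylation, mitochondrially encoded mRNAs, mitochondrial ribosome, glycolysis, hypoxia, NRF2, heme and iron, ferroptosis, cholesterol, fatty acids, PPAR targets, tricarboxylic acid cycle, p53, apoptosis, S phase, mitosis, immediate early genes, YAP, NF-kB, interferon, heat shock, metallothioneins, melanocyte lineage, dedifferentiation, ribosomal proteins, histones, structural noncoding RNAs, short-lived transcripts, and fibroblast, epithelial, leukocyte and endothelial markers. Each median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries and not as a test across samples.

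Named genes were the 12 highest and 12 lowest log2 ratios with a mean of at least 5 FPKM for each comparison with control, and the 5 highest and 5 lowest for the other contrasts. For each list they were up to 4 members with the largest absolute log2 ratio and a mean of at least 1 FPKM, and for the additive fit the 5 with the smallest adjusted p in each direction. Members of the mitophagy, integrated stress response, heme and iron, and cholesterol lists could be named freely, and subsets were taken from the top of each order, except that a few genes are not reported here. The 6 lineage genes without reads, the expressed markers of the lineage and other-cell lists, and KRT31 in the DHA fit were named after their values were seen.

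Among the alternative settings, those fixed in that way were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, rescaling by median of ratios or to equal totals, size rules of 1.5-fold and 4-fold, limma without trend, and random lists not matched on expression. Voom on recovered reads, protein-coding genes alone, removal of the exon-length trend over 20 bins, and a minimum of 200 reads over the 4 libraries were chosen after seeing the data. Left out were fits without 1 library, which would have no residual degree of freedom, and strand-resolved readings of antisense genes. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.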

Results

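RNA was sequenced from OMM2.3, an established uveal melanoma line derived from a liver metastasis, in 4 libraries with 1 library in each group. The groups were control cells, cells given CCCP, cells given DHA, and cells given CCCP and DHA together. CCCP (carbonyl cyanide m-chlorophenyl hydrazone) is a protonophore that dissipates the mitochondrial membrane potential and so uncouples respiration from ATP synthesis. The labels do not spell out DHA, and doses, times and the treatment of the control are not given in the sources used here. Reads summed over genes numbered 18937286 in control, 16942245 with CCCP, 17347602 with DHA and 16900411 with both. Protein-coding genes held 97.7, 97.2, 97.5 and 97% of them in the same order. With 1 library per group, no spread between replicates could be measured, and the intervals given with fold differences are 95% exact binomial intervals that cover counting error only.

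Most melanocyte lineage transcripts were scarce in this line. Of 22 lineage and pigmentation genes, 16 lay under 1 FPKM in all 4 libraries, and 6 of these, PAX3, TYR, OCA2, SLC45A2, EDNRB and KIT, had 0 reads throughout. A count of 0 allowed up to 0.165 FPKM (3 reads) among the low genes. The lineage regulator MITF was present at 8.81 FPKM in control, 8.89 with CCCP, 7.35 with DHA and 5.01 with both. The other genes at 1 FPKM or more were GPNMB, GPR143, RAB27A, RAB38 and PMEL. The 6 measured members had median log2 ratios to control of 0.15 with CCCP, -0.05 with DHA and -0.35 with both.

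Markers of other cell types were mostly low as well. No leukocyte marker of 13 and no endothelial marker of 8 reached 1 FPKM, with highest values of 0.442 and 0.164 FPKM. Epithelial markers included the simple-epithelium keratins KRT8, KRT18 and KRT7, and KRT8 reached 195 FPKM. Of 12 fibroblast markers, 4 were measured (COL1A1, PDGFRB, FAP and FBN1). Their median log2 ratios to control were -0.69, -0.50 and -1.30 with CCCP, DHA and both, and those of the epithelial markers were -0.38, -0.12 and -0.49. COL1A1, which encodes a chain of type I collagen, had log2 ratios of -1.62, -1.86 and -3.34.

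CCCP alone against control addressed the response to the uncoupler. Among genes with a mean of at least 5 FPKM the highest ratio was that of CYP1A1, a xenobiotic-metabolizing cytochrome P450 (ENSG00000140465, chromosome 15, 74719542 to 74725610 on GRCh38). Its level was 1.03 FPKM in control and 76.5 with CCCP, 74.2-fold (58.5 to 95.5) higher. SERPINB2, which encodes an inhibitor of plasminogen activators, was 12.5-fold (10.6 to 14.9) higher. CEMIP, which takes part in hyaluronan breakdown, was 4.58-fold (4.16 to 5.05) higher. The hair keratin genes KRT34 and KRT31 and the keratin-associated gene KRTAP2-3 were 3.95-fold (3.69 to 4.22), 3.56-fold (2.6 to 4.93) and 4.07-fold (3.66 to 4.54) higher. OTUD1, a deubiquitinase, and CYP24A1, the vitamin D hydroxylase, were 3.85-fold (3.41 to 4.36) and 3.34-fold (3.23 to 3.46) higher. Among noncoding transcripts, AC004057.1 was 7.35-fold (6.32 to 8.59) and RN7SL2, a signal recognition particle RNA, 5.71-fold (4.8 to 6.83) higher. RNU6-1016P went from 0 reads in control to 11, and MIR6827 was 3.96-fold (1.4 to 13.7) higher.

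On the lower side with CCCP, PMEPA1, a TGF-beta target that feeds back on the pathway, was 5.41-fold (5.0 to 5.87) lower, and the crosslinking enzyme gene TGM2 was 3.31-fold (3.12 to 3.5) lower. PFKFB3 and PFKFB4, whose enzymes set the level of the glycolytic activator fructose-2,6-bisphosphate, were 3.26-fold (3.0 to 3.55) and 3.55-fold (3.08 to 4.11) lower. The coactivator gene NCOA5, the adhesion gene AMIGO2 and the splicing factor gene HNRNPM were 4.22-fold (3.49 to 5.15), 3.23-fold (2.8 to 3.74) and 2.84-fold (2.69 to 3.01) lower. AC245041.1, SPCS2P4 and RF02247 were 4.99-fold (3.98 to 6.34), 4.68-fold (3.72 to 5.95) and 3.15-fold (1.75 to 6.0) lower. The small nuclear RNA RNU1-106P rested on 18 reads in control and 1 with CCCP, and the interval of MIR5587 included 1.

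S phase, glycolysis and hypoxia genes had the lowest medians with CCCP among lists with at least 6 measured genes. The 22 glycolysis genes had a median log2 ratio of -0.55 (percentile 0 of matched random lists), and 20 of them lay below control. Besides PFKFB3 and PFKFB4, LDHA, the lactate dehydrogenase gene, was at -1.28 and PGK1 at -1.04. All 21 hypoxia-response genes, 4 of which are on the glycolysis list too, lay below control, with a median of -0.54 and CA9 at -1.46, BHLHE40 at -1.40 and BNIP3 at -1.25. DNA replication and S phase genes had a median of -0.65 over 26 genes, with UHRF1 at -1.17 and CDC6 at -0.94, whereas the 27 mitosis genes had a median of -0.05. Endoplasmic reticulum chaperones had a median of -0.43, led by HSPA5 (BiP) at -0.99.

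Several groups lay above control with CCCP. YAP and TEAD targets had a median log2 ratio of 0.40 over 19 genes, with CYR61 at 1.34, ANKRD1 at 1.22 and TGFB2 at 1.07. Integrated stress response genes, the targets of the transcription factor ATF4, had a median of 0.42, but only 2 of 26 were at least 2-fold higher (ATF3 and STC2) and DDIT4, a hypoxia-inducible inhibitor of mTOR signalling, was at -1.48. NRF2 targets had a median of 0.28, with NQO1 at 1.32 and FTL at 1.31. Mitophagy genes had a median of 0.23 over 22 genes (percentile 99.7), with the kinase gene PINK1 at 0.57 and the receptor gene OPTN at 0.56, against BNIP3 and BNIP3L at -1.25 and -0.54. NF-kB and inflammatory genes had a median of 0.38, with IL1B at 1.65, but it turned to -0.24 among genes with a mean of at least 5 FPKM. In all, 439 genes were at least 2-fold higher and 317 lower, of which 216 and 156 had an interval excluding 1 and 72 and 62 were protein coding. Counting noise alone gave 132 and 133 over all genes, and 0.2 and 0.15 among protein-coding genes.

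DHA alone against control addressed the response to the other compound, and its main feature was a higher level of integrated stress response genes. PSAT1, an enzyme of serine synthesis (ENSG00000135069, chromosome 9, 78297143 to 78330093 on GRCh38), went from 22.7 to 144 FPKM and was 6.31-fold (5.9 to 6.77) higher. SLC7A11, the cystine transporter, CTH, which makes cysteine, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, were 4.54-fold (4.14 to 4.99), 4.76-fold (3.54 to 6.52) and 3.81-fold (3.39 to 4.29) higher. The amino acid transporter gene SLC7A5 and the pseudokinase gene TRIB3 were 3.56-fold (3.37 to 3.76) and 3.48-fold (3.06 to 3.97) higher. KRT34 was 4.74-fold (4.44 to 5.06) higher, and RN7SL2 and AC004057.1 were 6.22-fold (5.24 to 7.43) and 5.85-fold (5.02 to 6.85) higher, as with CCCP. RNU6-1016P went from 0 to 8 reads.

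Of the 26 measured integrated stress response genes, 19 were at least 2-fold higher with DHA, with a median log2 ratio of 1.22 (percentile 100 of random lists). CHAC1, a glutathione-degrading enzyme gene, was at 2.47. The ferroptosis list held 3 genes at least 2-fold higher, CHAC1, SLC7A11 and SLC3A2, all of them also integrated stress response genes, and its median was 0.10. NRF2 targets had a median of 0.22, with NQO1 after SLC7A11 at 1.06. Lipid synthesis genes lay lower. Cholesterol genes had a median of -0.22 (percentile 0) with HMGCS1 at -0.71, and fatty acid synthesis genes -0.17 with GPAM at -0.81. Endoplasmic reticulum chaperones had a median of -0.20, with PDIA4 at -0.69.

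Few protein-coding genes were at least 2-fold lower with DHA. Among genes with a mean of at least 5 FPKM the 4 lowest ratios, in AP001052.1, MT-TE, MIR3936 and SNORD94, rested on 14, 12, 20 and 20 control reads. The thymosin gene TMSB15A was 2.35-fold (1.68 to 3.33) lower, the interval of SNORD14A included 1, and the tetraspanin gene TSPAN13 was 2.0-fold (1.84 to 2.18) lower. Mitosis genes had a median of -0.20 (percentile 0), 24 of 27 below control, and S phase genes -0.12 (percentile 0.03), while hypoxia and mitophagy genes had medians of -0.03 and 0.05. In all, 274 genes were at least 2-fold higher and 255 lower, of which 126 and 73 had an interval excluding 1 and 39 and 8 were protein coding. Counting noise alone gave 134 and 127 over all genes, and 0.25 and 0.1 among protein-coding genes.

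The combination against control addressed the joint response, which was the broadest of the comparisons with control. CYP1A1 and SERPINB2 were 48.3-fold (38 to 62.2) and 26.8-fold (22.8 to 31.8) higher. PTX3, a secreted pattern recognition protein gene, was 31.4-fold (23.3 to 43.2) and LURAP1L 26-fold (20.2 to 34) higher. KRT34 reached 669 FPKM from 32.9, 20.3-fold (19.1 to 21.6) higher, and KRT31 was 14.4-fold (10.9 to 19.4) higher. The stress genes TRIB3, SLC7A11, CTH, PSAT1 and DDIT3, the last encoding the proapoptotic factor CHOP, were 16.6-fold (14.8 to 18.6), 13.2-fold (12.1 to 14.4), 15.1-fold (11.5 to 20.3), 9.19-fold (8.59 to 9.83) and 11.4-fold (9.61 to 13.7) higher. RNU6-1016P, the remaining gene of the 12 highest with a mean of at least 5 FPKM, had 15 reads.

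CA9, the hypoxia-induced carbonic anhydrase (ENSG00000107159, chromosome 9, 35673856 to 35681159 on GRCh38), went from 48 to 2.15 FPKM with the combination and was 22.3-fold (17.3 to 29.3) lower. The mitochondrial transfer RNAs MT-TR and MT-TG were 10.4-fold (3.81 to 39.8) and 6.03-fold (2.35 to 19.7) lower on few reads. TMSB15A, the developmental regulator gene LBH and IGFBP5, which encodes a binding protein of insulin-like growth factors, were 12.8-fold (6.54 to 28.6), 7.25-fold (6.75 to 7.8) and 8.67-fold (7.17 to 10.6) lower. SPCS2P4, LINC01638 and the sense intronic gene AC037198.1, whose reads are not told from those of an overlapping gene, were 7.6-fold (5.75 to 10.2), 8.51-fold (5.36 to 14.2) and 6.18-fold (4.43 to 8.85) lower. PMEPA1 was 5.51-fold (5.1 to 5.97), the carboxypeptidase gene CPA4 5.63-fold (4.95 to 6.42) and the hypoxia-induced repressor gene BHLHE40 5.44-fold (4.84 to 6.12) lower.

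Integrated stress response genes reached a median log2 ratio of 2.24 with the combination, and 23 of 26 were at least 2-fold higher. Cell cycle genes had the lowest medians among lists with at least 6 measured genes. The 27 mitosis genes had a median of -1.18, with 19 at least 2-fold lower, among them KIF20A at -2.11, BIRC5 at -1.71, CCNA2 at -1.64 and the proliferation marker MKI67 at -1.64. The 26 S phase genes had a median of -1.19, with 18 at least 2-fold lower and UHRF1 at -1.94. Glycolysis genes had a median of -1.03 with 12 of 22 at least 2-fold lower, LDHA at -1.99. Hypoxia genes had a median of -0.70, with 8 of 21 at least 2-fold lower and 1, VEGFA, higher at 1.23.

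**Figure D1:**
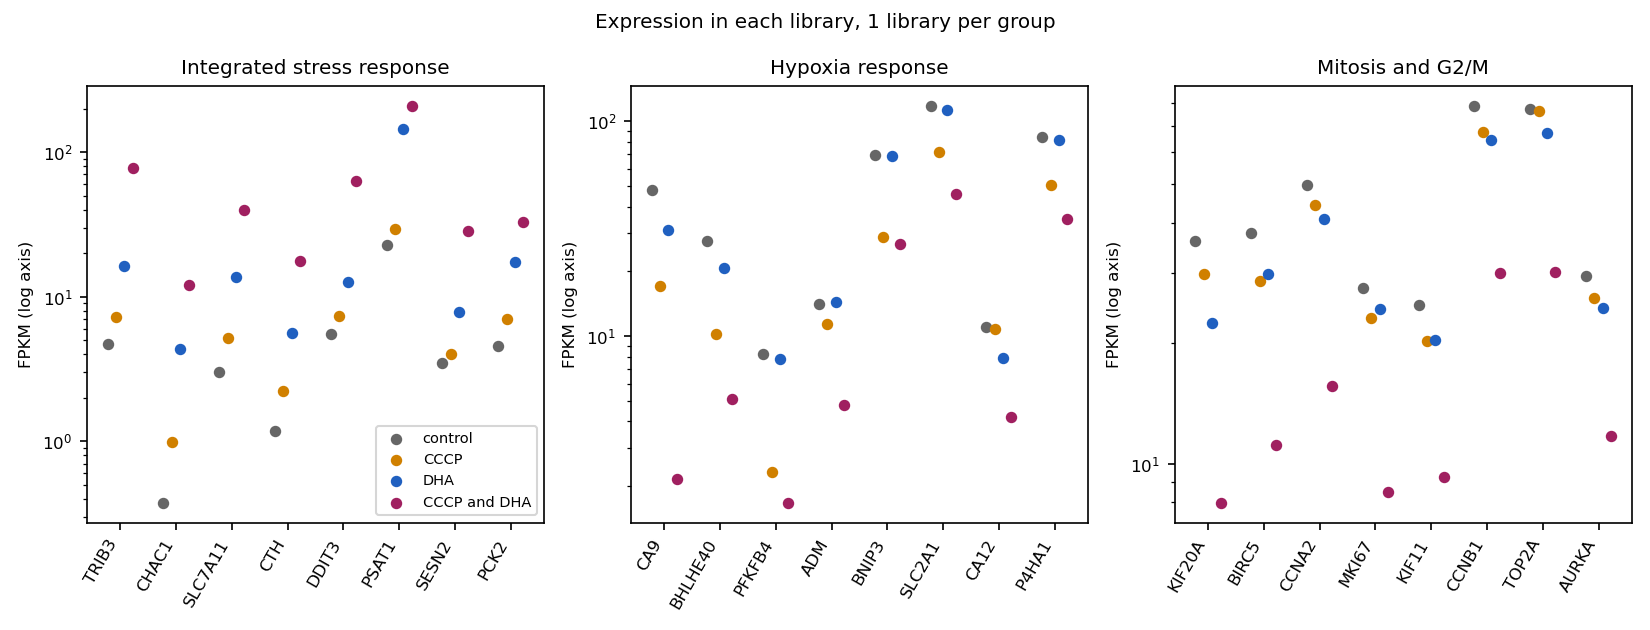
Level in FPKM (log axis) of the 8 genes in each of the integrated stress response, hypoxia and mitosis lists with the largest absolute log2 ratio of combination to control, in each of the 4 libraries, 1 point per library. CA9 lay at 48 FPKM in control and 2.15 with the combination.

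Of the other stress and inflammatory groups with the combination, some lay above the random range and some within it. NF-kB and inflammatory genes had a median of 1.12 over 16 genes, with IL1A at 3.92, IL1B at 3.35 and IL6 at 2.19. NRF2 targets, which include SLC7A11, had a median of 0.91, with NQO1 at 2.44 and FTL at 1.83, and the ferroptosis list 0.34. In the heme and iron list, whose median of 0.07 lay within the range of random lists (percentile 70.8), FTL and FTH1, the ferritin chains, were at 1.83 and 1.51, and ALAS1, the first enzyme of heme synthesis, at 1.14. Mitophagy genes had a median of 0.11 (percentile 84.5), with SQSTM1 at 1.65 and BNIP3 at -1.37, and autophagy machinery 0.19 (percentile 94.3), with MAP1LC3B at 1.79. The p53 targets had a median of 0.43, with GADD45A at 1.93 and the proapoptotic gene BBC3 at 1.10. Short-lived transcripts, a sign of how RNA was handled, had a median of 0.45 in the same library. Their list overlaps the integrated stress response list, with ATF3 on both. With DHA, none of the 20 measured short-lived transcripts was at least 2-fold higher, against 19 of 26 integrated stress response genes. Those 19 are thus not on both lists, and a difference in RNA handling of the combination library is not set aside.

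Cholesterol genes had a median log2 ratio of -0.48 with the combination, with INSIG1, a sterol-responsive gene, at -1.29. Fatty acid synthesis genes had a median of -0.36, with FADS2 at -1.50. Endoplasmic reticulum chaperone and unfolded protein response genes went both ways, with a median of -0.34, PDIA4 and CALR at -1.89 and -1.88, and 7 of 20 above control, the highest at 0.95. The 13 mitochondrially encoded mRNAs had a median of -0.53, with MT-CO2 at -0.97, while 3 lay above control, the highest at 0.30. Mitochondrial genes held 3.85% of reads with the combination, 4.8% in control, 5.09% with CCCP and 5.18% with DHA. In all, 618 genes were at least 2-fold higher and 744 lower than control, of which 404 and 569 had an interval excluding 1 and 238 and 406 were protein coding. Counting noise alone gave 135 and 128 over all genes, and 0.2 and 0.1 among protein-coding genes.

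**Figure D2:**
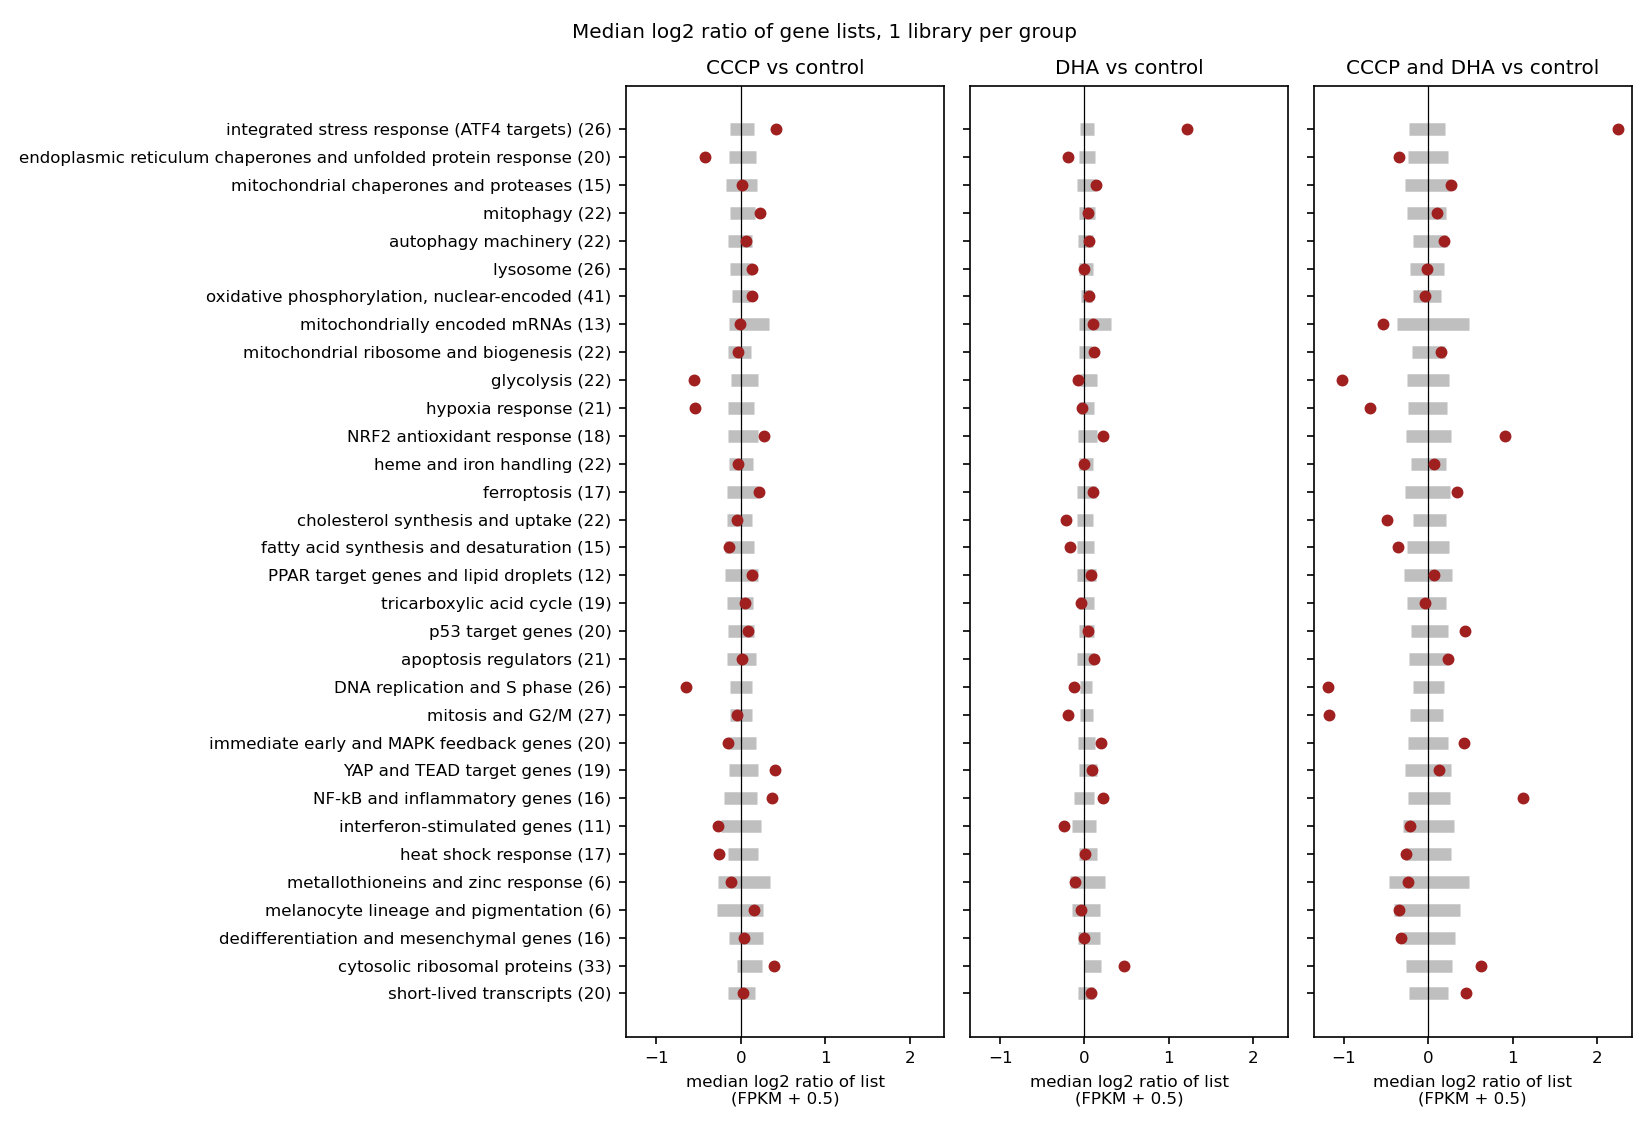
Median log2 ratio to control of each gene list with at least 6 measured genes for CCCP, DHA and the combination, with the middle 95% of 10000 matched random lists as grey bars. Integrated stress response genes lay at 2.24 and mitosis genes at -1.18 with the combination.

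The combination against CCCP alone addressed what DHA added to the uncoupler. PTX3 was 15.3-fold (12.2 to 19.5), TRIB3 10.6-fold (9.63 to 11.8), DDIT3 8.54-fold (7.25 to 10.1) and LURAP1L 7.99-fold (6.83 to 9.39) higher, and RNU1-106P had 20 reads against 1. IGFBP5 was 17.3-fold (14.4 to 21), CEMIP 10.5-fold (9.13 to 12.2), CA9 7.95-fold (6.09 to 10.5), TMSB15A 9.76-fold (4.9 to 22.1) and MT-TG 9.5-fold (3.79 to 30.6) lower. Of the 26 integrated stress response genes, 23 were at least 2-fold higher, with a median log2 ratio of 1.77, and the mitosis genes had a median of -1.16. In all, 473 genes were at least 2-fold higher and 676 lower, 170 and 311 of them protein coding, against 154 and 152 over all genes and 0.3 and 0.4 among protein-coding genes from counting noise.

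The combination against DHA alone addressed what the uncoupler added. CYP1A1 was 68.6-fold (50.8 to 95), SERPINB2 12.9-fold (11.4 to 14.7), PTX3 13.6-fold (11 to 17) and LURAP1L 8.24-fold (7.04 to 9.69) higher, and AP001052.1 had 13 reads against 1. CA9 was 14.5-fold (11.2 to 19.1), MT-TR 7.76-fold (2.74 to 30.3), LBH 5.27-fold (4.89 to 5.68), the natriuretic peptide gene NPPB 6.15-fold (3.86 to 10.3) and IGFBP5 6.24-fold (5.13 to 7.64) lower. S phase, mitosis, glycolysis and hypoxia genes had median log2 ratios of -1.12, -0.97, -0.94 and -0.69, and integrated stress response genes 0.89. In all, 447 genes were at least 2-fold higher and 497 lower, 105 and 214 of them protein coding, against 148 and 149 over all genes and 0.3 and 0.25 among protein-coding genes from counting noise.

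Each compound was present in 2 of the 4 libraries, and an additive limma-trend fit tested its effect over both pairs. The fit has 1 residual degree of freedom, and takes the departure from additivity as the spread between replicates. With CCCP, 5 genes rose and 8 fell past an adjusted p of 0.05, each in the same direction in both pairs. CYP1A1 (log2 5.51, SE 0.14, adjusted p 0.000222), SERPINB2 (log2 3.51, SE 0.14, adjusted p 0.00134), KRT34 (log2 2.03, SE 0.17, adjusted p 0.0282), KRT31 and the antisense gene AC089983.1 rose. The kit named in the protocol does not mark strand, so reads of AC089983.1 are not told from those of the gene it overlaps. PMEPA1 (log2 -2.08, SE 0.18, adjusted p 0.0282), PFKFB3 (log2 -1.60, SE 0.13, adjusted p 0.0282), PFKFB4, SPCS2P4 and RF02247 were among those that fell. With DHA, 13 genes rose and 1 fell. PSAT1 (log2 2.72, SE 0.16, adjusted p 0.0285), KRT34, PCK2, CHAC1 (log2 2.77, SE 0.20, adjusted p 0.0323) and PHGDH, which opens serine synthesis, led the rise, and COL1A1 fell (log2 -1.79, SE 0.17, adjusted p 0.0385). KRT34 and KRT31 rose with both compounds.

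Over all genes tested, 9 of the 26 integrated stress response genes rose with DHA, and 24 adjusted over the list alone. Of the same genes, 20 rose with CCCP adjusted over the list alone, and none over all genes. With CCCP, 2 glycolysis genes fell over all genes and 14 of 22 adjusted over the list alone, against 1 and 15 of 21 hypoxia genes and 0 and 23 of 26 S phase genes. The 1 hypoxia gene, PFKFB4, is also 1 of the glycolysis genes. In the same order, 0 and 7 NF-kB genes and 0 and 7 NRF2 targets rose with CCCP. In simulated libraries with 200 changed genes per factor, 17.8% of CCCP calls and 17.6% of DHA calls were false at a dispersion of 0.01, and 34.5 and 37.8% at 0.04. With nothing changed, the same fit made 4 CCCP and 6 DHA calls. The false shares of CCCP and DHA calls were 4.81 and 3.94% at 0.01 and 7.05 and 4.64% at 0.04 with voom, and 7.8 and 5.58% and 7.89 and 6.21% among protein-coding genes. The simulated effects were additive, without interaction, and were placed on genes with a mean of at least 5 FPKM. Each fit takes the interaction as its spread, so these shares are not error rates of the calls in the real libraries. The numbers of genes rising and falling became 192 and 327 for CCCP and 179 and 230 for DHA with equal totals, 297 and 388 for CCCP and 232 and 301 for DHA with voom on recovered reads, 85 and 150 for CCCP and 50 and 13 for DHA among protein-coding genes, 3 and 8 for CCCP and 1 and 0 for DHA without the exon-length trend, and 0 without the filter or without the variance trend.

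Treatment effects without and with the other compound were compared across genes, which are not independent replicates. The effect of CCCP in libraries without DHA correlated with that in libraries with DHA at Pearson r 0.254 (Spearman rho 0.32), and the effect of DHA at 0.253 (rho 0.356), against -0.0129 in simulated unchanged libraries. Among genes with a mean of at least 5 FPKM r was 0.474 and 0.537. CCCP took 39%, DHA 37.7% and their interaction 23.3% of the variation, where noise alone gave the interaction 33.6%. The single effects against the shared control correlated at 0.395, below the simulated 0.462 of unchanged libraries, but their covariance of 0.0823 exceeded the simulated 0.0378 by 0.0445. The orthogonal main effects correlated at 0.221 (simulated -0.0401) and at 0.495 among genes with a mean of at least 5 FPKM. The control and combination libraries enter both main effects with the same sign. A deviation particular to either library raises this correlation, so it does not show alone that the compounds moved the same genes. Genes at least 2-fold higher with both single treatments numbered 108 (simulated 59.7, independent 8.79), and 106 were lower with both (simulated 47.6, independent 5.91). The simulated values hold counting noise only, and the independent values leave out the shared control. Any other deviation of the control library raises the covariance and these overlaps, so they do not show a shared response either.

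Cell cycle, stress, inflammatory and mitochondrially encoded genes departed from the sum of the single effects. All 27 mitosis genes had a negative interaction, 10 of them at least 2-fold, with a median of -0.88. Their combination median of -1.18 compared with -0.30 for the sum of the single log2 ratios. S phase genes had a median interaction of -0.51. Integrated stress response genes went the other way, with a median interaction of 0.40, 25 of 26 above 0, and a combination median of 2.24 against a sum of 1.71. Median interactions were 0.52 for NF-kB genes, 0.34 for immediate early and MAPK feedback genes and 0.32 for the ferroptosis list. The ferroptosis median is the value of SLC3A2, which with CHAC1 and SLC7A11 is also on the integrated stress response list, so it partly repeats that result. Median interactions were 0.20 for NRF2 targets, which include SLC7A11, 0.19 for p53 targets, and -0.57 for mitochondrially encoded mRNAs, of which 2 of 13 lay above 0. Endoplasmic reticulum chaperone and unfolded protein response genes went both ways, with a median of 0.17 and 11 above 0 against 9 below. Short-lived transcripts, a sign of RNA handling whose list shares ATF3 with that of the stress response, were at 0.18 (random lists -0.22 to 0.13). The median interactions of YAP and TEAD targets (-0.31, random lists -0.30 to 0.07), glycolysis genes (-0.30, random lists -0.28 to 0.04) and nuclear-encoded oxidative phosphorylation genes (-0.20, random lists -0.19 to 0.04) lay barely outside the middle 95% of random lists. Among single genes with a mean of at least 5 FPKM the highest interactions were in RNU1-106P (2.83), PTX3 (2.75), AP001052.1 (2.51), the transferrin receptor gene TFRC (2.18) and DDIT3 (1.87). The lowest were in AC004057.1 (-4.65), RN7SL2 (-3.21), IGFBP5 (-3.15), RNU6-1016P, on few reads, and NPPB (-2.81). With 1 library per group no interaction could be tested, and across all genes the combination correlated with the sum at 0.604, a value that the shared control raises.

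**Figure D3:**
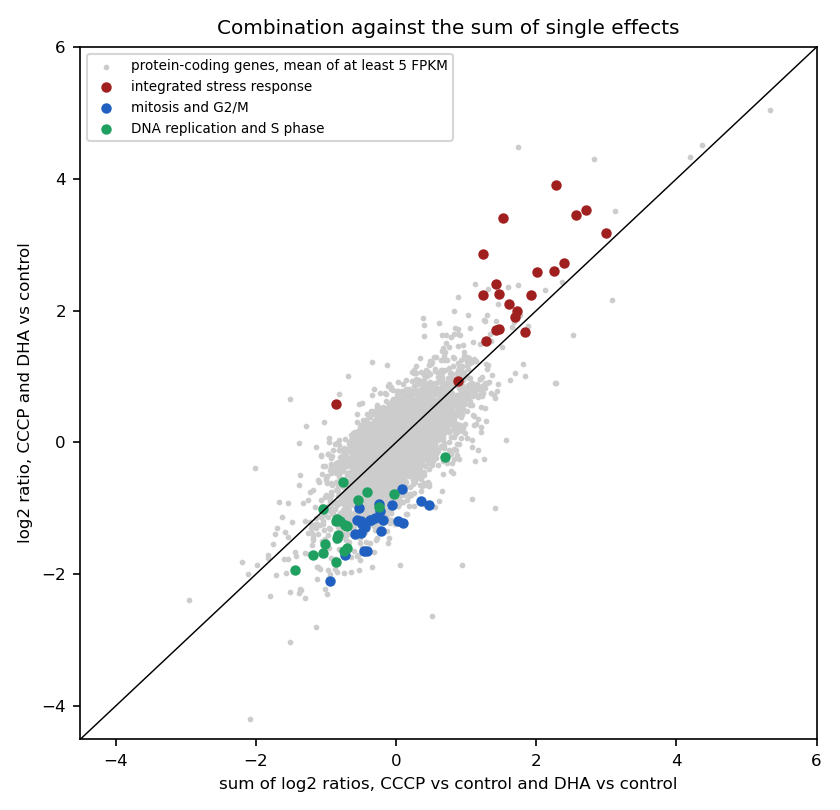
Log2 ratio of combination to control against the sum of the single log2 ratios, 1 point per protein-coding gene with a mean of at least 5 FPKM, with the line of equality. Mitosis genes lay below the line, with a median interaction of -0.88, and integrated stress response genes mostly above it, with 0.40.

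Among the remaining groups, nuclear-encoded oxidative phosphorylation genes had median log2 ratios to control of 0.13, 0.05 and -0.04 with CCCP, DHA and both, tricarboxylic acid cycle genes 0.04, -0.04 and -0.03, mitochondrial ribosome and biogenesis genes -0.04, 0.11 and 0.16, and mitochondrial chaperones and proteases 0.01, 0.14 and 0.26, with HSPA9 at 1.28 in the combination. Lysosome genes had medians of 0.13, -0.00 and -0.02, PPAR targets and lipid droplet genes 0.13, 0.08 and 0.07, and apoptosis regulators 0.02, 0.11 and 0.24. Interferon-stimulated genes had medians of -0.27, -0.24 and -0.22, heat shock genes -0.25, 0.01 and -0.26, and metallothioneins -0.11, -0.11 and -0.24. Dedifferentiation and mesenchymal genes had medians of 0.04, -0.00 and -0.33. Immediate early and MAPK feedback genes had medians of -0.15, 0.19 and 0.43, the last at percentile 99.9 of matched random lists, with DUSP5 at 1.81 in the combination.

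The treated libraries were set against the same control library for ribosomal protein genes and signs of RNA handling, so that their agreement rests on 1 control. All 33 ribosomal protein genes lay above control in each treated library, with medians of 0.39, 0.47 and 0.62, and with RPS18 at 0.85 in the combination. The 4 structural noncoding RNAs, a sign of how RNA was selected, had medians of 0.85, 0.54 and 1.14, with RN7SL2 at 2.49, 2.62 and 1.90. The 3 replication-dependent histone genes had medians of -0.06, -0.52 and -0.38. Short-lived transcripts had medians of 0.03, 0.08 and 0.45, with the last at percentile 100. In the combination ATF3, also an integrated stress response gene, and KLF4 were at 2.24 and 1.61. The 10 most abundant genes held 7.52, 8.93, 7.75 and 8.2% of reads in control, CCCP, DHA and the combination.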

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

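The tests on melanocyte markers and on mitosis and integrated stress response genes were chosen only after the results were seen. Named genes with a mean of at least 5 FPKM and at least 200 reads over the 4 libraries numbered 310. Of these, 9 had effects of a compound at least 1.5-fold in opposite directions without and with the other compound. The naming rule took in the 5 highest and 5 lowest interactions, so opposite effects were partly selected for. Each effect came from 1 library per group, and none of these differences was tested. AC004057.1 had a CCCP log2 ratio of 2.85 without and -1.81 with DHA, and a DHA ratio of 2.52 without and -2.14 with CCCP, a difference of -4.65. RN7SL2 had CCCP ratios of 2.49 and -0.72 and DHA ratios of 2.62 and -0.59, a difference of -3.21. For RPL7AP6, a ribosomal protein pseudogene, the CCCP ratio was 1.16 without and -0.73 with DHA (difference -1.89). In AC004057.1, RN7SL2 and RPL7AP6 the control library was the lowest, at 20.3, 26.5 and 19.8 FPKM. Their higher single ratios thus share 1 low control value, and RN7SL2 is also among the structural noncoding RNAs taken as a sign of RNA selection. IGFBP5 had CCCP ratios of 0.96 and -2.19 (difference -3.15), and IFI6, an interferon-induced gene, 0.63 and -0.88 (difference -1.51). TFRC, the transferrin receptor gene, went the opposite way, with -1.33 and 0.85 (difference 2.18). So did VEGFA, with -0.88 and 0.69 (difference 1.57), the heme oxygenase gene HMOX1, with -0.73 and 0.81 (difference 1.54), and the chemokine gene CXCL8, with -0.91 and 0.78 (difference 1.69).

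Most melanocyte lineage transcripts, though not MITF or GPNMB, were near zero in a line labelled as ocular melanoma. Depth is excluded, since 3 reads stood for at most 0.165 FPKM among the low markers. Cells of another origin, or a dedifferentiated state of the line, may explain the 16 markers under 1 FPKM in all 4 libraries, and cannot be told apart without genotypes or another sample of the line. Leukocyte and endothelial markers all lay under 1 FPKM, but 4 of 11 epithelial and 4 of 12 fibroblast markers reached it, with highest values of 195 and 40.4 FPKM. No biological explanation was tested, as the design has 1 line.

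Mitosis genes lay below, and integrated stress response genes above, the sum of the single effects. On the FPKM scale, the median ratio of the combination to the sum of the single changes was 0.545 (0.453 to 0.562) for mitosis genes. Their single effects were small, with medians of -0.05 and -0.20, so both scales expect nearly the same value. The log scale is thus excluded as the cause, but this ratio restates the interaction and adds no separate evidence. For integrated stress response genes that ratio, 1.65, decides nothing, as single effects above control with a positive interaction fix it above 1. After removal of the exon-length trend the median interactions were -0.87 (-1.14 to -0.80) and 0.38 (0.28 to 0.77). They were -0.88 and 0.40 before it, so this trend was not the whole cause in these libraries. The intervals in this paragraph come from resampling the genes of each list. These genes are not independent replicates, and the intervals cover no spread between libraries. A joint action of the compounds could explain both groups. It cannot be told apart from a difference of a library other than its treatment, such as cell density, harvest or RNA handling. The number of combination libraries was 1, as for each group, and all 4 libraries enter the interaction with the same weight.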

How the results depend on the processing

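Voom, protein-coding genes alone, removal of the exon-length trend and the minimum of 200 reads were tests chosen only after the results were seen. No paired analysis was possible because each group had 1 library and no replicate number to block on, apart from the additive fit, which sets each compound against its absence at both levels of the other. Rescaling by median of ratios tested nothing, since the deposited values already carried those factors, and a factor per library moves a list and its random lists alike. Without both rescalings, the medians of gene lists kept their direction and side of the random range in 1350 of 1420 values, with 43 weaker, 26 stronger and 1 reversed. The reversed median was that of NF-kB genes for CCCP against control, -0.24 among genes with a mean of at least 5 FPKM, a filter that leaves out IL1A and IL1B. Without median of ratios, of 8445 log2 ratios of named genes, 8064 stayed within the size of their counting interval, 381 moved further and 0 of those at least 2-fold changed direction. Leaving out a library was not run, as it leaves no residual degree of freedom, and depth limits mainly the noncoding genes of few reads.

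With a pseudocount of 0.1, 2-fold genes numbered 516 lower for CCCP against control and 422 lower for DHA against control, calls of the fit (higher and lower) 6 and 15 for CCCP and 14 and 2 for DHA, and r of the orthogonal factors 0.119. A pseudocount of 1 gave 262 and 178 for CCCP against control, 176 and 150 for DHA against control, 449 lower for the combination against CCCP and 297 and 322 for the combination against DHA (higher and lower where paired), and fit calls of 8 and 16 for CCCP and 12 and 0 for DHA. Without the filter the numbers were 501 lower for CCCP against control, 456 and 431 for DHA against control, 750 higher for the combination against CCCP and 736 higher for the combination against DHA, and fit calls 0 and 0 for CCCP and 0 and 0 for DHA. Stricter filters test fewer genes. A mean of at least 5 FPKM gave 60 and 46 for CCCP against control, 50 and 6 for DHA against control, 195 and 299 for the combination against control, 119 and 198 for the combination against CCCP and 68 and 184 for the combination against DHA, fit calls of 29 and 60 for CCCP and 30 and 4 for DHA, the interaction share 15.9%, r of the CCCP effects 0.474, r of the DHA effects 0.537 and r of the orthogonal factors 0.495. At least 200 reads gave 85 and 68 for CCCP against control, 53 and 7 for DHA against control, 270 and 423 for the combination against control, 174 and 315 for the combination against CCCP and 109 and 224 for the combination against DHA, fit calls of 77 and 130 for CCCP and 48 and 12 for DHA, the interaction share 16.7%, r of the CCCP effects 0.443, r of the DHA effects 0.512 and r of the orthogonal factors 0.432. Protein-coding genes alone gave 72 and 62 for CCCP against control, 39 and 8 for DHA against control, 238 and 406 for the combination against control, 170 and 311 for the combination against CCCP and 105 and 214 for the combination against DHA, fit calls of 85 and 150 for CCCP and 50 and 13 for DHA, the interaction share 16.8%, r of the CCCP effects 0.44, r of the DHA effects 0.523 and r of the orthogonal factors 0.423. A 1.5-fold rule gave by construction more genes, 1073 and 883 for CCCP against control, 606 and 568 for DHA against control, 1517 and 1742 for the combination against control, 1213 and 1698 for the combination against CCCP and 1045 and 1283 for the combination against DHA, and a 4-fold rule fewer, 74 and 46 for CCCP against control, 45 and 53 for DHA against control, 120 and 90 for the combination against control, 97 and 100 for the combination against CCCP and 99 and 49 for the combination against DHA. Fit calls were 192 and 327 for CCCP and 179 and 230 for DHA with equal totals, 297 and 388 for CCCP and 232 and 301 for DHA with voom, 0 and 0 for CCCP and 0 and 0 for DHA without the variance trend and 3 and 8 for CCCP and 1 and 0 for DHA without the exon-length trend. The balance of 2-fold genes turned for CCCP against control, with 376 higher and 389 lower with equal totals and 313 higher and 444 lower without the exon-length trend, and for DHA against control, with 247 higher and 291 lower and 239 higher and 313 lower. It also turned for DHA against control with a pseudocount of 0.1, with 406 higher and 422 lower, for the combination against DHA, with 474 higher and 429 lower with equal totals and 736 higher and 687 lower without the filter, and under the 4-fold rule for DHA against control, the combination against control and the combination against DHA. Called again were 13 of 13 CCCP calls and 14 of 14 DHA calls with equal totals, 10 of 13 CCCP calls and 12 of 14 DHA calls with voom and 10 of 13 CCCP calls and 1 of 14 DHA calls without the exon-length trend. For the pseudocounts, the missing filter, the scaling and the other fits the cause was not tested, nor was it for the calls of the fit, shares and correlations under stricter filters.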

Other observations

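The tests on CYP1A1 were chosen only after the result was seen, while the TGF-beta test was chosen after PMEPA1, TGM2 and FOXS1 had been seen but before the values of its target genes were. CYP1A1 is a classical target of the aryl hydrocarbon receptor, a ligand-activated transcription factor. Of 6 other targets, 4 had a counting interval above 1 both in CCCP against control and in the combination against DHA. They were CYP1B1, with folds of 3.0 (2.41 to 3.74) and 2.54 (1.89 to 3.45), TIPARP, with 1.65 (1.55 to 1.76) and 1.78 (1.67 to 1.9), the receptor repressor gene AHRR, with 3.25 (2.01 to 5.42) and 3.57 (1.94 to 6.98), and NQO1, with 2.51 (2.4 to 2.62) and 2.61 (2.53 to 2.7). Reads of the paralog CYP1A2 came to 0.296% of those of CYP1A1 in the CCCP library, which excludes shared reads as the cause. The interval of a single library pair covers counting error only, and 1688 of all 13678 genes tested (12.3%) and 17.1% of those with a mean of at least 5 FPKM met the same condition. AHRR, CYP1A2 and ALDH3A1 lay under the filter of 1 FPKM and so outside these sets. NQO1, also an NRF2 target, had been seen as higher before, and whether the receptor was active in the libraries with CCCP stays open.

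PMEPA1, TGM2 and FOXS1, all known as TGF-beta targets, were lower in both libraries with CCCP. Over 17 other measured TGF-beta targets the median log2 ratio was -0.34 for CCCP against control and -0.36 for the combination against DHA, at percentiles 0.01 and 0.1 of matched random lists. The list held only targets not looked at before, so it leaves out targets whose values had been seen, higher or lower. COL5A1, a fibrillar collagen gene, was at -1.34 and -1.23, LTBP2 at -1.02 and -1.02, and NOX4 at -0.99 and -1.17. Other targets went the opposite way in both comparisons, among them BAMBI at 0.83 and 0.53 and TGFB1I1 at 0.42 and 0.40. Some changed direction between the comparisons, such as TAGLN at 1.28 and -0.11 and SKIL at -0.30 and 0.12. SMAD7 was at -0.34 and -0.14, with a counting interval that included 1 in the second comparison. Fibroblast markers, 4 of them measured, were lower too, with medians of -0.69 (percentile 0.02) and -0.81 (percentile 0.08). Lower TGF-beta signalling with CCCP may account for the lower targets as a hypothesis, but not for those that were higher, and a change in cells with fibroblast-like expression or a difference between libraries other than treatment was not tested.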
